A study of Mus musculus with 43 samples.

How the data were processed

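The series holds strand-specific mRNA sequencing of mouse lung in 43 libraries: saline (7), house dust mite (HDM) for 4 weeks (10), HDM for 15 weeks (7), 15 weeks plus an isotype control antibody (4) and 15 weeks plus anti-IL-33 (15). Per the labels the libraries were made from lung total RNA with a stranded mRNA kit, and the genome build was GRCm38. The aligner, the counting tool, the annotation, the strand setting and any filter are not given in the sources used here. The authors deposited raw counts per Entrez gene ID, as whole numbers without normalization. The table has 24475 IDs, of which 24375 were matched to a gene in the annotation used here and 100 were not. The unmatched IDs hold 2.62% of all counts, nearly all of them on ID 100861531. They were kept in the library totals.

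Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and Python 3.11.15 with NumPy 2.4.6 and matplotlib 3.10.9 for figures. Library sizes were scaled by TMM, and genes with too few counts were removed with edgeR's filterByExpr, which left 15598 genes. All 43 libraries entered 1 edgeR quasi-likelihood fit with robust spread, with a term for each group and a term for the 2 ranges into which the sample numbers fall. Each of the 6 comparisons is a contrast in that fit. Genes with a Benjamini-Hochberg (BH) adjusted p under 0.05 are said to rise, fall or change. The labels give no pairing, so no paired analysis was made. What the number ranges stand for is not given in the sources used here.

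Gene lists, 31 in all, were fixed before the data were examined, as were the tests, the comparisons and the rule for named genes. The rule named the 6 genes with the largest rise and the 6 with the largest fall among called genes with a mean of at least 2 CPM in the higher group, leaving out predicted, clone-named, immunoglobulin and T cell receptor segment genes. It added up to 4 members with the smallest p from each list that camera called. It added up to 3 from the type 2, alternatively activated macrophage, goblet, neutrophil-attracting and matrix lists whether called or not, and a fixed set of names for 15 weeks against saline and anti-IL-33 against isotype. Of the fixed names, Epx had too few counts and Igha and Ighe are not in the table. Genes named outside that rule were chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01, with BH over the 31 lists within a comparison, and again with an estimated correlation and with fry. At the preset correlation random regroupings of the libraries also gave many calls, as described below, so those p-values alone are weak evidence. Counts of list members are given over all genes and again with adjustment over the list alone.

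The analysis was tested on simulated data with known changes, where it recovered 77.6% of 2-fold changes for 15 weeks against saline, 83.6% for 4 weeks against saline, 88.1% for 15 against 4 weeks, 80.6% for anti-IL-33 against isotype, 65.7% for isotype against no antibody and 91.0% for anti-IL-33 against saline. Of 1.5-fold changes it recovered 26.9% for isotype against no antibody and 53.7% to 65.7% in the other comparisons. The share of calls that were false, at a nominal 5%, was 7.95% for 15 against 4 weeks, 6.11% for isotype against no antibody, 6.08% for anti-IL-33 against saline and 3.11% to 4.32% in the other 3. In each comparison only 67, 67 and 66 of 15598 genes were changed 1.5-, 2- and 4-fold. Counts were drawn independently for each gene, with no library set apart from its group. Most real comparisons call a far larger share of genes, so these rates need not hold for the real data. Alternatives tried were other size factors, other filters, no term for the number ranges, each number range alone, only the 2 groups compared, a surrogate variable, limma-voom, DESeq2, a fold threshold, other controls for the antibody, and leaving out each isotype library. Alternatives without 2 libraries that stand apart and with counts corrected for GC content and gene length were added after the data were seen. Gene positions are those of GRCm38.p6. Reads of genes with near-identical copies, and of genes that overlap another gene, may be assigned unevenly.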

Results

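Lung gene expression was measured by strand-specific mRNA sequencing in 43 libraries from mice exposed to house dust mite (HDM), an airway allergen, or to saline. All mice carried a humanised Il33 gene on a mixed C57BL/6NTac and 129S6SvEvTac background. IL-33 is an alarmin cytokine released by damaged epithelial and other barrier cells. The groups held 7 saline libraries, 10 libraries after 4 weeks of HDM, 7 after 15 weeks of HDM without antibody, 4 after 15 weeks with an isotype control antibody and 15 after 15 weeks with an anti-IL-33 antibody. Total counts per library (M, mega-counts) ranged from 7.09 to 12.4 M in saline, 4.80 to 11.96 M at 4 weeks, 4.91 to 11.5 M at 15 weeks, 8.35 to 10.2 M with the isotype and 5.13 to 12.6 M with anti-IL-33. The saline libraries carry no time label, so time in the study or age cannot be told apart from HDM in the contrasts with saline. The sample numbers in the labels fall in 2 separate ranges, called number ranges 1 and 2 here, with 22 and 21 libraries, and every group has libraries in both. Values per group are counts per M (CPM) with the SD over libraries, and log2 fold changes carry the SE of the fit. Adjusted p-values are Benjamini-Hochberg (BH) values from edgeR's quasi-likelihood test, or from camera for gene lists. The p-values measure the spread between samples, and counting error alone is smaller than that spread.

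Along the first principal component, which held 36.6% of the variance, saline libraries averaged -68.6 ± 8.21 (SD, n = 7), 4-week libraries 17.6 ± 19.4 (n = 10) and 15-week libraries 40.4 ± 22.8 (n = 7). Isotype libraries averaged 33.9 ± 13.9 (n = 4) and anti-IL-33 libraries -7.64 ± 22.5 (n = 15). The axis shows where libraries lie and was not tested.

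**Figure D1:**
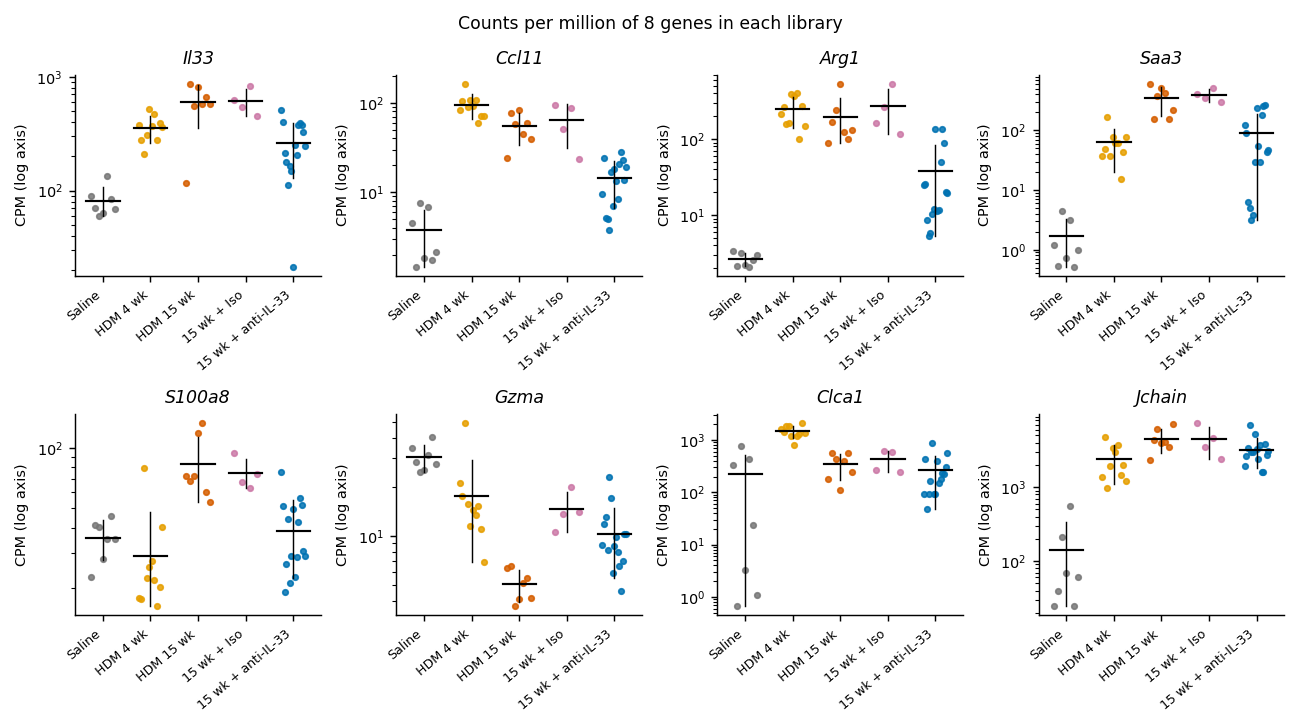
Counts per M of Il33, Ccl11, Arg1, Saa3, S100a8, Gzma, Clca1 and Jchain in each library, on a log axis, for the 5 groups (points, libraries; horizontal bars, means; vertical bars, 1 SD either side, ending at the lowest library where the SD would pass it). Clca1 spans 0.674 to 754 CPM in the saline libraries, and Arg1 averages 269 CPM with the isotype and 37.8 CPM with anti-IL-33.

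The first comparison asked what 4 weeks of HDM changed in the lung. Ccl11, an eosinophil-attracting chemokine (Entrez 20292, chromosome 11, 82057832 to 82062955, GRCm38), averaged 95.1 ± 29.01 CPM (SD, n = 10) after HDM and 3.75 ± 2.61 CPM (n = 7) in saline. Its log2 fold change was 4.66 ± 0.43 (SE), and all 10 HDM libraries were above every saline library. The macrophage genes Arg1 and Mmp12, the goblet cell gene Slc26a4, the cell cycle gene Aurkb and the plasma cell gene Mzb1 also rose. The NK receptor gene Ncr1, the type I alveolar marker Rtkn2, the ciliated cell gene Dnah11 and the endothelial gene Kdr fell. By edgeR, 4573 of 15598 tested genes were higher and 4293 lower at an adjusted p under 0.05, and 2027 of these changed at least 2-fold. With counts corrected for GC content and gene length the balance turned, to 4512 higher and 4549 lower. Of the 8866 genes called in the main fit, 7078 stayed called under that correction and 8484 kept their sign.

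Type 2 cytokines, chemokines and receptors had a median log2 fold change of 2.92, and 13 of the 14 measured members rose (13 adjusted over the list alone). Ccl8 rose by 5.83 ± 0.42 and Ccl24 by 5.56 ± 0.60 on the log2 scale. Among alternatively activated macrophage genes 13 of 14 rose (14 adjusted over the list alone), with a median of 3.88. They included Mmp12, a macrophage elastase, at 6.38 ± 0.72, and Pdcd1lg2, the PD-L2 gene, at 2.83 ± 0.21. Monocyte and interstitial macrophage markers rose in 8 of 13 and fell in 1, with the same counts adjusted over the list alone, among them Ms4a7 at 3.22 ± 0.19 and the complement gene C1qb at 2.57 ± 0.17. camera called these 3 lists (adjusted p = 1.26e-09, 9.82e-12 and 2.61e-08), and the calls held with an estimated correlation (adjusted p = 0.0184, 0.0184 and 0.0491). They were the only camera calls in this comparison that held that way. In the IL-33 and alarmin list 6 of 9 members rose and 1 fell (6 and 2 adjusted over the list alone), with Il1rl1, the IL-33 receptor, at 2.09 ± 0.25 and Il33 itself at 2.15 ± 0.35 (camera adjusted p = 0.0253, and adjusted p = 0.115 with an estimated correlation). What the counts of the humanised Il33 gene align to is not given in the sources used here, so Il33 values here and below carry that limit.

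Goblet cell and mucus genes rose in 14 of 15 (14 adjusted over the list alone; camera adjusted p = 2.99e-07, and adjusted p = 0.109 with an estimated correlation). Slc26a4, the anion exchanger pendrin, rose by 4.67 ± 0.44 and Agr2, a mucin-folding protein, by 2.72 ± 0.41. The goblet cell gene Clca1 ranged from 0.674 to 754 CPM among the 7 saline libraries. Neutrophil-attracting and IL-17/IL-1 family mediators rose in 12 of 13 (12 adjusted over the list alone), including Cxcl5 at 4.29 ± 0.66 and Il6 at 3.14 ± 0.47 (camera adjusted p = 3.51e-05, and adjusted p = 0.207 with an estimated correlation). Matrix and airway remodelling genes rose in 16 of 20 (16 adjusted over the list alone), with the glycoprotein gene Tnc at 2.01 ± 0.25 and Col3a1 at 1.33 ± 0.19 (camera adjusted p = 3.58e-05, and adjusted p = 0.214 with an estimated correlation). All 17 proliferation genes rose, also adjusted over the list alone, for example Aurkb at 1.85 ± 0.18 (camera adjusted p = 1.28e-14, and adjusted p = 0.0707 with an estimated correlation). Complement and acute phase genes rose in 9 of 14 and fell in 2, the same adjusted over the list alone, with C3 at 1.83 ± 0.16 (camera adjusted p = 1.06e-05, and adjusted p = 0.0831 with an estimated correlation).

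Plasma cell markers rose in 8 of 10 (8 adjusted over the list alone), with Mzb1 at 3.79 ± 0.37 and Jchain, the joining chain of secreted IgA and IgM, at 4.10 ± 0.53 (camera adjusted p = 1.01e-06, and adjusted p = 0.115 with an estimated correlation). Jchain was the 1 measured member of the immunoglobulin constant list (camera adjusted p = 0.0377, and adjusted p = 0.109 with an estimated correlation), whose other members are not in the table and were not analysed here. B cell markers rose in 9 of 10 (10 adjusted over the list alone; camera adjusted p = 0.00107, and adjusted p = 0.286 with an estimated correlation), and lymphoid aggregate genes in 10 of 13 (10 adjusted over the list alone; camera adjusted p = 0.000469, and adjusted p = 0.120 with an estimated correlation). Among T cell markers 10 of 14 rose and 2 fell (10 and 3 adjusted over the list alone). Cd4 rose by 1.19 ± 0.17 and Foxp3, the regulatory T cell factor, by 1.33 ± 0.20, while Cd8a fell by 0.67 (camera adjusted p = 0.00352, and adjusted p = 0.352 with an estimated correlation). Eosinophil markers rose in 6 of 9 and fell in 1, with the same counts adjusted over the list alone, and Prg2, the eosinophil major basic protein, rose by 4.76 ± 0.34 (camera adjusted p = 0.00324, and adjusted p = 0.0912 with an estimated correlation). Dendritic cell markers rose in 8 of 12 and fell in 1, the same adjusted over the list alone, with Batf3 at 2.56 ± 0.20 (camera adjusted p = 0.000397, and adjusted p = 0.0852 with an estimated correlation). The mast cell protease gene Mcpt2 rose by 7.33 ± 0.93, from 0.0517 ± 0.0658 CPM in saline to 8.88 ± 4.83 CPM. Mcpt2 belongs to a protease family with close copies. The mast cell and basophil list as a whole was not called (5 of 12 rose and 2 fell, also adjusted over the list alone; camera adjusted p = 0.0777).

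NK and cytotoxic markers fell in 8 of 10 (8 adjusted over the list alone), with the NK receptor gene Ncr1 at -1.56 ± 0.26 and Prf1 at -1.09 ± 0.22 (camera adjusted p = 0.000808, and adjusted p = 0.207 with an estimated correlation). Type I alveolar markers fell in 8 of 11 and 1 rose, the same adjusted over the list alone, with Rtkn2 at -1.40 ± 0.19 (camera adjusted p = 0.000135, and adjusted p = 0.126 with an estimated correlation). Type II alveolar markers rose in 7 of 11 (7 adjusted over the list alone), with surfactant protein gene Sftpd at 1.57 ± 0.20 (camera adjusted p = 0.0146, and adjusted p = 0.286 with an estimated correlation). Ciliated cell markers fell in 10 of 12 (11 adjusted over the list alone), with the dynein gene Dnah11 at -1.22 ± 0.21 (camera adjusted p = 0.00107, and adjusted p = 0.298 with an estimated correlation). Endothelial markers fell in 7 of 13 (7 adjusted over the list alone), with Kdr at -1.32 ± 0.20 (camera adjusted p = 0.00882, and adjusted p = 0.334 with an estimated correlation). Genes with the deepest falls included Fabp1 at -4.84 ± 0.45, Asgr1 at -4.57 ± 0.48 and the sulfotransferase gene Sult1d1 at -3.44 ± 0.36. The lists of interferon response, neutrophil, alveolar macrophage, club cell, and fibroblast and smooth muscle genes were not called (camera adjusted p = 0.991, 0.547, 0.685, 0.0777 and 0.756). The interferon and neutrophil medians (-0.15 and -0.12) lay below 0 while their means (0.16 and 0.35) and tests pointed up, and the cardiac median was -0.29 with a mean of 0.02. Markers of other tissues were not called either: cardiac muscle adjusted p = 0.468, red blood cells 0.0777 and fat 0.495. Outside these lists, the skeletal muscle myosin genes Myh8 and Myh1 were among the 6 largest rises by the fixed rule. They lay above the saline mean in only 4 and 3 of the 10 libraries, and the source of this was not tested. Immediate early genes had an adjusted p of 0.179. Within number range 1 (4 against 2 libraries) 2309 genes passed and within range 2 (6 against 5) 9285, and Ccl11 rose by 5.21 and 4.41 in them. Without the 2 libraries that stand apart from their groups, 15-week HDM replicate 1 and 4-week HDM replicate 3, 9843 genes passed.

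The second comparison asked what 15 weeks of HDM changed. Arg1, the arginase of alternatively activated macrophages (Entrez 11846, chromosome 10, 24915207 to 24927470), rose from 2.66 ± 0.52 CPM (SD, n = 7) in saline to 197 ± 154 CPM (n = 7), a log2 fold change of 6.34 ± 0.79. The acute phase gene Saa3 rose by 7.79 ± 0.99, from 1.67 ± 1.55 to 351 ± 179 CPM, and all 7 HDM libraries exceeded every saline library for both genes. The neutrophil-associated gene Lcn2, the matrix gene Timp1 and the plasma cell gene Derl3 rose, while the NK cell genes Gzma and Ncr1 fell. edgeR called 4859 of 15598 genes higher and 4376 lower, with 2991 changed at least 2-fold. After the GC and length correction 4452 were higher and 4921 lower. Of the 9235 genes called in the main fit, 7410 stayed called and 8853 kept their sign.

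All 13 measured neutrophil-attracting and IL-17/IL-1 family mediators rose, also adjusted over the list alone, with a median of 3.98. Lcn2 rose by 4.72 ± 0.46, Il6 by 3.98 ± 0.50, Cxcl1 by 3.61 ± 0.47 and Tnf by 2.16 ± 0.30 (camera adjusted p = 1.32e-07, and adjusted p = 0.130 with an estimated correlation). Neutrophil markers rose in 9 of 11 (9 adjusted over the list alone), with the decoy receptor gene Il1r2 at 2.78 ± 0.41, Ly6g at 2.56 ± 0.57 and S100a8 at 1.11 ± 0.31 (camera adjusted p = 0.0358, and adjusted p = 0.303 with an estimated correlation). Type 2 genes rose in 12 of 14 and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.000229, and adjusted p = 0.130 with an estimated correlation). Among them Il13, the cytokine that drives goblet cells, rose by 3.91 ± 0.71 and Il5 by 1.98 ± 0.62. Both had low counts, at 1.84 ± 0.81 and 0.65 ± 0.33 CPM after HDM. Il4 rose by 1.61 ± 0.50 and Ccl11 by 3.88 ± 0.44. Il33 rose by 2.998 ± 0.39, with the limit given above, and Il1rl1 by 1.57 ± 0.27, and the alarmin list rose in 5 of 9 and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.0494, and adjusted p = 0.172 with an estimated correlation). Alternatively activated macrophage genes rose in 13 of 14 (13 adjusted over the list alone), with the chitinase-like gene Chil3 at 4.04 ± 0.52 and Retnla at 2.20 ± 0.70 (camera adjusted p = 3.07e-06, and adjusted p = 0.120 with an estimated correlation). Goblet genes rose in 10 of 15 (12 adjusted over the list alone), with Slc26a4 at 4.51 ± 0.46, while Muc5ac (0.73 ± 0.50, adjusted p = 0.208) and Clca1 (0.73 ± 0.81, adjusted p = 0.446) did not pass beside saline libraries that spanned 0.674 to 754 CPM of Clca1 (camera adjusted p = 0.000916, and adjusted p = 0.30 with an estimated correlation). Ifng, the type 1 cytokine, did not pass (-0.17 ± 0.63).

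Matrix genes rose in 15 of 20 and fell in 1 (16 and 1 adjusted over the list alone), with Timp1 at 4.16 ± 0.58, Tnc at 2.55 ± 0.28 and Col1a1 at 1.60 ± 0.30 (camera adjusted p = 6.11e-05, and adjusted p = 0.261 with an estimated correlation). Plasma cell markers rose in 9 of 10 (9 adjusted over the list alone), with Derl3 at 4.49 ± 0.38 and Jchain at 5.03 ± 0.58, which alone makes up the immunoglobulin constant list (camera adjusted p = 0.0363, and adjusted p = 0.130 with an estimated correlation). The plasma cell list was called (camera adjusted p = 1.58e-09, and adjusted p = 0.0957 with an estimated correlation). Proliferation genes rose in 16 of 17 (16 adjusted over the list alone; camera adjusted p = 1.83e-07, and adjusted p = 0.172 with an estimated correlation), complement and acute phase genes in 10 of 14 with 1 lower, the same adjusted over the list alone (camera adjusted p = 3.22e-07, and adjusted p = 0.0957 with an estimated correlation). Monocyte and interstitial macrophage markers rose in 7 of 13 and fell in 1, the same adjusted over the list alone (camera adjusted p = 6.58e-06, and adjusted p = 0.125 with an estimated correlation). Lymphoid aggregate genes rose in 8 of 13 (8 adjusted over the list alone; camera adjusted p = 0.0374, and adjusted p = 0.303 with an estimated correlation). All 11 type II alveolar markers rose, also adjusted over the list alone, with Sftpd at 1.94 ± 0.22 (camera adjusted p = 0.000229, and adjusted p = 0.130 with an estimated correlation). Genes with the highest rises by the fixed rule included Awat1, an acyltransferase gene, at 7.96 ± 0.86, the phosphate-regulating hormone gene Fgf23 at 7.78 ± 1.03 and the neuropeptide gene Npy at 7.45 ± 1.09.

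All 10 NK and cytotoxic markers fell, also adjusted over the list alone, with a median of -2.52. Gzma, a cytotoxic granule protease (Entrez 14938, chromosome 13, 113093824 to 113100981), went from 30.4 ± 5.68 to 5.08 ± 1.13 CPM, a log2 fold change of -2.82 ± 0.28, and Ncr1 fell by 3.47 (camera adjusted p = 6.64e-08, and adjusted p = 0.0957 with an estimated correlation). Type I alveolar markers fell in 10 of 11 (10 adjusted over the list alone), with Hopx at -1.92 ± 0.21 (camera adjusted p = 1.62e-05, and adjusted p = 0.130 with an estimated correlation). Ciliated markers fell in 11 of 12 (12 adjusted over the list alone; camera adjusted p = 6.11e-05, and adjusted p = 0.247 with an estimated correlation), and endothelial markers in 10 of 13 (10 adjusted over the list alone), with the angiopoietin receptor gene Tek at -2.11 ± 0.27 (camera adjusted p = 0.000916, and adjusted p = 0.261 with an estimated correlation). Fibroblast and smooth muscle markers fell in 5 of 13 (5 adjusted over the list alone), with Inmt at -2.74 ± 0.31 and Pdgfra at -1.59 ± 0.18 (camera adjusted p = 0.0358, and adjusted p = 0.303 with an estimated correlation). Markers of other tissues moved with these lists: cardiac muscle genes fell in 8 of 10 (8 adjusted over the list alone), with Tnnt2 at -1.47 ± 0.28 (camera adjusted p = 0.0106, and adjusted p = 0.303 with an estimated correlation). Red blood cell genes fell in 6 of 9 (6 adjusted over the list alone), with Hbb-bt at -2.25 ± 0.52 (camera adjusted p = 0.0429, and adjusted p = 0.395 with an estimated correlation). Globin genes have near-identical copies whose reads may be split between them. Fat markers were not called (adjusted p = 0.121). Also not called were interferon response genes (2 of 17 rose and 10 fell, adjusted p = 0.0913), eosinophil (0.0856), mast cell (0.515), T cell (0.339), B cell (0.347), alveolar macrophage (0.447), dendritic cell (0.0516), club cell (0.0503) and immediate early genes (0.0810). None of the camera calls at 15 weeks against saline held with an estimated correlation. The library that stands apart, 15-week HDM replicate 1, differed from the other 6 in the direction of 6 of these calls, by medians of 0.98 in type II alveolar, 0.96 in goblet, 0.80 in complement, 0.73 in matrix, 0.23 in plasma cell and -0.54 in ciliated genes. Each stayed a camera call without the 2 libraries that stand apart. Within number range 1 (5 against 2 libraries) 4194 genes passed and within range 2 (2 against 5) 6912, with Arg1 at 6.38 and 5.48 and Gzma at -2.61 in both. Without the 2 libraries that stand apart 9820 genes passed.

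The 4-week and 15-week effects overlapped widely. Both exposures raised 3541 genes and lowered 3326 in common, where 1425 and 1204 would be shared by unrelated lists of these sizes. Only 24 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.859 with a covariance of 0.713. Part of that comes from the shared saline libraries: simulated unchanged groups against the same saline libraries gave a mean covariance of 0.0342 and r = 0.525. They gave no shared calls, which was fixed in advance, since no group was changed, and is no reference for the shared genes. Simulated counts were drawn independently for each gene, so variation that genes share between saline libraries was absent. With the saline libraries divided between the 2 contrasts, 5252 genes were shared, against 916 and 783 expected in the 2 directions, and the covariance was 0.725. The overlap without the 2 libraries that stand apart was 7898 genes.

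The comparison of 15 with 4 weeks of HDM asked how lungs after the longer exposure differed from those after the shorter. No saline libraries are labelled by time, so length of exposure cannot be told apart from time in the study or age. Ccl24, a chemokine for eosinophils, was lower after 15 weeks, at 6.59 ± 7.11 CPM (SD, n = 7) against 43.8 ± 23.7 CPM (n = 10), a log2 fold change of -2.87 ± 0.50. Cxcl2, a neutrophil chemokine, was higher, at 13.7 ± 11.6 against 2.33 ± 1.79 CPM (2.87 ± 0.59). Gzma was lower by -1.87 ± 0.26 and Sdc1, a plasma cell surface proteoglycan, higher by 0.97 ± 0.16. The isotype libraries, also at 15 weeks, did not share this low Gzma. They averaged 14.6 ± 4.00 CPM (n = 4), near the 17.6 ± 11.8 CPM at 4 weeks, against 5.08 ± 1.13 CPM without antibody. edgeR called 3334 genes, 1918 higher and 1416 lower, and 507 differed at least 2-fold. The balance turned here too with GC content and length corrected, to 1913 higher and 2126 lower. Of the 3334 genes called in the main fit, 2715 stayed called and all kept their sign.

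Type 2 genes fell in 8 of 14 and none rose (11 fell adjusted over the list alone), including Gata3 at -0.99 ± 0.18 and the eosinophil receptor gene Ccr3 at -1.66 ± 0.38 (camera adjusted p = 0.000166, and adjusted p = 0.30 with an estimated correlation). Alternatively activated macrophage genes fell in 7 of 14 and 1 rose (9 and 1 adjusted over the list alone), with Pdcd1lg2 at -1.12 ± 0.19 and Il4ra at 0.56 ± 0.14 (camera adjusted p = 0.00126, and adjusted p = 0.30 with an estimated correlation). Goblet genes fell in 4 of 15 and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0105, and adjusted p = 0.393 with an estimated correlation). Neutrophil-attracting mediators rose in 8 of 13 (10 adjusted over the list alone), with Tnf at 1.31 ± 0.26 and Il1b at 1.001 ± 0.24 (camera adjusted p = 3.94e-05, and adjusted p = 0.30 with an estimated correlation). Neutrophil markers rose in 5 of 11 and 1 fell (8 and 1 adjusted over the list alone). Csf3r, Mmp8 and S100a8 rose by 1.19 ± 0.21, 1.59 ± 0.29 and 1.47 ± 0.27, while Retnlg was at -1.41 ± 0.24 (camera adjusted p = 0.00105, and adjusted p = 0.30 with an estimated correlation). Complement and acute phase genes rose in 7 of 14 (8 adjusted over the list alone), with Hp at 1.22 ± 0.21 and Orm1 at 2.82 ± 0.64 (camera adjusted p = 0.00442, and adjusted p = 0.304 with an estimated correlation). Fga, the fibrinogen alpha chain, rose by 4.98 ± 0.62 to 18.4 ± 6.45 CPM, and it was higher in all 7 libraries at 15 weeks than in every library at 4 weeks.

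Plasma cell markers rose in 4 of 10 (8 adjusted over the list alone; camera adjusted p = 2.75e-05, and adjusted p = 0.30 with an estimated correlation), while B cell markers fell in 5 of 10 (6 adjusted over the list alone), with Pax5 at -1.54 ± 0.28 (camera adjusted p = 0.000351, and adjusted p = 0.306 with an estimated correlation). T cell markers fell in 6 of 14 (6 fell and 1 rose adjusted over the list alone), with Cd3g at -1.14 ± 0.21 (camera adjusted p = 0.00247, and adjusted p = 0.393 with an estimated correlation). NK markers fell in 9 of 10 (10 adjusted over the list alone; camera adjusted p = 2.00e-08, and adjusted p = 0.123 with an estimated correlation). In the isotype libraries, also at 15 weeks, this list was higher than without antibody, as described below. Interferon response genes fell in 6 of 17 (9 fell and 1 rose adjusted over the list alone), with Mx1 at -0.88 ± 0.20 (camera adjusted p = 0.00101, and adjusted p = 0.393 with an estimated correlation). Fibroblast and smooth muscle markers fell in 8 of 13 (9 adjusted over the list alone), with Tagln at -1.07 ± 0.18 (camera adjusted p = 1.51e-06, and adjusted p = 0.123 with an estimated correlation). Cardiac muscle genes fell beside them in 5 of 10 (6 adjusted over the list alone), with Actc1 at -1.37 ± 0.20 (camera adjusted p = 0.000233, and adjusted p = 0.30 with an estimated correlation). Type II alveolar markers rose in 5 of 11 (6 adjusted over the list alone), with the transporter gene Abca3 at 0.60 ± 0.14 (camera adjusted p = 0.00167, and adjusted p = 0.30 with an estimated correlation). The 15-week replicate 1, which stands apart, was 0.98 above the other 6 in the median of this list, and Abca3 was at 0.92 in number range 1, which holds it, and at 0.14 in range 2. Alveolar macrophage markers rose in 4 of 11 (4 adjusted over the list alone), with the scavenger receptor gene Marco at 2.71 ± 0.75 (camera adjusted p = 0.0227, and adjusted p = 0.393 with an estimated correlation). Smaller camera calls were falls in proliferation, mast cell, dendritic cell, type I alveolar, ciliated and endothelial lists (adjusted p = 0.00377, 0.0321, 0.0224, 0.0227, 0.0105 and 0.0228), with estimated-correlation adjusted p = 0.393, 0.393, 0.306, 0.393, 0.393 and 0.393. None of the 21 camera calls here held with an estimated correlation. Replicate 1 also differed from the other 6 in the direction of the complement (0.80), alveolar macrophage (0.32), interferon (-1.03), proliferation (-0.90), ciliated (-0.54), B cell (-0.37), alternatively activated macrophage (-0.24), plasma cell (0.23), dendritic cell (-0.21), type 2 (-0.04) and mast cell calls (-0.03). The mast cell list was not called without the 2 libraries that stand apart (adjusted p = 0.0751), while the others and the type II list were. Immunoglobulin constant (adjusted p = 0.288), matrix (0.257), lymphoid aggregate (0.0801), alarmin (0.830), eosinophil (0.0592), monocyte (0.407), club cell (0.257), red blood cell (0.256), fat (0.0698) and immediate early lists (0.228) were not called. Within number range 1 (5 against 4 libraries) 1409 genes passed and within range 2 (2 against 6) 149, with Ccl24 at -2.79 and -3.05 and Cxcl2 at 3.17 and 1.34. Without the 2 libraries that stand apart 2733 genes passed, and 1206 with only these 2 groups in the fit.

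**Figure D2:**
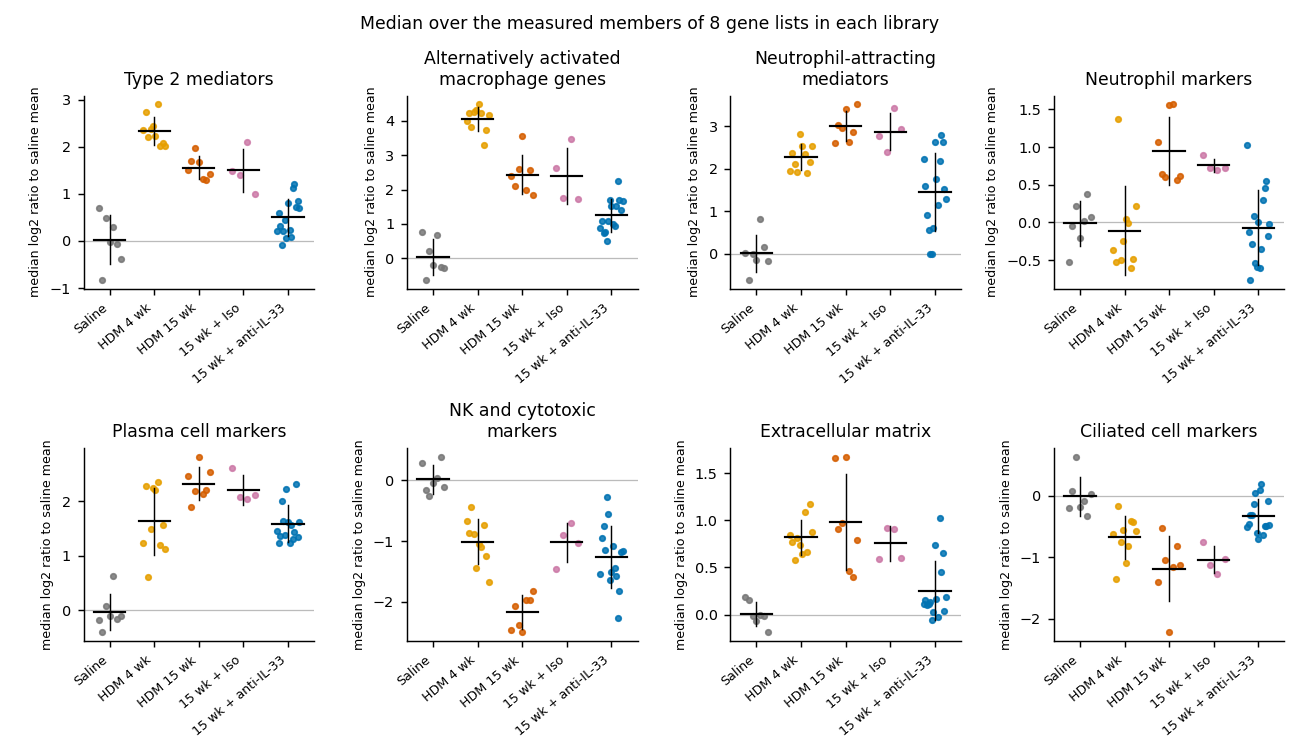
Median over the measured members of 8 gene lists in each library, as the log2 ratio to the saline mean, for the 5 groups (points, libraries; horizontal bars, means; vertical bars, 1 SD either side). NK and cytotoxic markers lie lowest after 15 weeks of HDM without antibody, where all 10 members fell against saline.

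The comparison of anti-IL-33 with the isotype control at 15 weeks asked what blocking IL-33 changed in the chronically exposed lung. Arg1 averaged 37.8 ± 45.3 CPM (SD, n = 15) with anti-IL-33 and 269 ± 188 CPM (n = 4) with the isotype, a log2 fold change of -2.93 ± 0.57. Ccl11 fell from 64.3 ± 33.1 to 14.5 ± 7.79 CPM (-2.15 ± 0.37). Il13 and Il5 were lower by -2.56 ± 0.55 and -2.68 ± 0.56, both near the floor. Il13 averaged 2.07 ± 0.89 CPM with the isotype and 0.32 ± 0.38 CPM with anti-IL-33, and Il5 1.03 ± 0.69 and 0.14 ± 0.16 CPM. The neutrophil chemokine gene Cxcl2 was lower by -2.76 ± 0.60. Dnah5 and Dnah9, dynein genes of ciliated cells, were higher. edgeR called 557 of 15598 genes higher and 489 lower, with 277 changed at least 2-fold. This balance of calls rested on single libraries, with 7 higher and 87 lower without isotype replicate 1, 540 and 395 without replicate 2, 10 and 48 without replicate 3, and 302 and 381 without replicate 4. It was 101 and 196 in number range 1 and 430 and 522 with limma-voom. Libraries outside the comparison moved it too. It was 1984 and 2169 with only these 2 groups in the fit, and 2308 and 2331 without the 2 libraries that stand apart. All 1046 called genes kept their sign without isotype replicate 1, 3 or 4, and 1041 did without replicate 2. Those fits share most libraries with the main fit, so kept signs are partly built in.

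Type 2 genes fell in 5 of 14 (6 adjusted over the list alone; camera adjusted p = 2.53e-06, and adjusted p = 0.0934 with an estimated correlation). Il1rl1 fell by 1.25, in all 15 libraries below the isotype mean, while Il4 (-0.86 ± 0.50, adjusted p = 0.256) and Ccl17 (-0.67 ± 0.36, adjusted p = 0.207) did not pass. In the alarmin list Il33, Il1rl1 and Il7r fell, 3 of 9 members (5 adjusted over the list alone), with Il33, under the same limit, at -1.33 ± 0.35 (camera adjusted p = 0.00104, and adjusted p = 0.0832 with an estimated correlation). Il33 (Entrez 77125, chromosome 19, 29925113 to 29960718) averaged 611 ± 162 CPM with the isotype, 261 ± 132 CPM with anti-IL-33 and 81.3 ± 25.2 CPM in saline. Alternatively activated macrophage genes fell in 6 of 14 (8 adjusted over the list alone), with Mmp12 at -2.51 ± 0.58, Ccl24 at -2.63 ± 0.62 and Retnla at -2.26 ± 0.67 (camera adjusted p = 2.53e-06, and adjusted p = 0.0934 with an estimated correlation). Chil3 did not pass (-0.59 ± 0.47, adjusted p = 0.407). Il13ra2, the decoy receptor for IL-13, was the named gene with the deepest fall, -3.41 ± 0.51. Its counts were low, at 4.41 ± 3.73 CPM with the isotype (0.688 to 9.12) and 0.348 ± 0.278 CPM with anti-IL-33. Goblet genes were not called as a list (adjusted p = 0.261), and 1 of 15 fell, Slc26a4 at -1.84 ± 0.37 (also 1 adjusted over the list alone). Muc5ac (0.47 ± 0.52) and Clca1 (-0.72 ± 0.81) did not pass.

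Neutrophil-attracting mediators fell in 7 of 13 (10 adjusted over the list alone), with Il1b at -1.18 ± 0.25, Cxcl3 at -1.65 ± 0.41 and Il6 at -1.64 ± 0.44 (camera adjusted p = 2.13e-09, and adjusted p = 0.0934 with an estimated correlation). Tnf (-0.80 ± 0.27), Cxcl1 (-1.12 ± 0.39) and Il17a (-1.48 ± 0.83) did not pass. Neutrophil markers fell in 6 of 11 (7 adjusted over the list alone), with Retnlg at -1.36 ± 0.25, the chemokine receptor gene Cxcr2 at -1.07 ± 0.23 and S100a8 at -0.92 ± 0.29 (camera adjusted p = 6.49e-06, and adjusted p = 0.0934 with an estimated correlation). Ly6g did not pass (-0.63 ± 0.49). Matrix genes fell in 5 of 20 (8 adjusted over the list alone), with Timp1 at -2.29 ± 0.49 and Col3a1 at -0.70 ± 0.20 (camera adjusted p = 6.14e-06, and adjusted p = 0.332 with an estimated correlation). Col1a1 did not pass (-0.58 ± 0.28, adjusted p = 0.174). Complement and acute phase genes fell in 2 of 14 (2 adjusted over the list alone), C3 at -0.77 ± 0.17 and Saa3 at -2.19 ± 0.67 (camera adjusted p = 0.00765, and adjusted p = 0.389 with an estimated correlation). Plasma cell markers fell in 3 of 10 (4 adjusted over the list alone), with Xbp1 at -0.53 ± 0.17 (camera adjusted p = 0.00193, and adjusted p = 0.465 with an estimated correlation). Type II alveolar markers fell in 2 of 11 (4 adjusted over the list alone; camera adjusted p = 0.0103, and adjusted p = 0.426 with an estimated correlation) and immediate early genes in 2 of 12 (3 adjusted over the list alone), with Atf3 at -1.27 ± 0.27 (camera adjusted p = 0.0106, and adjusted p = 0.489 with an estimated correlation).

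Ciliated cell markers rose in 4 of 12 (9 adjusted over the list alone), with Dnah5 at 1.06 ± 0.27 and Dnah9 at 0.90 ± 0.23 (camera adjusted p = 8.78e-06, and adjusted p = 0.332 with an estimated correlation). All 15 anti-IL-33 libraries were above every isotype library for Dnah5. Type I alveolar markers rose in 2 of 11 (4 adjusted over the list alone), Rtkn2 at 0.85 ± 0.23 and Clic5 at 0.83 ± 0.25 (camera adjusted p = 0.0366, and adjusted p = 0.576 with an estimated correlation). The transcription factor gene Zbtb16 rose by 2.14 ± 0.44 and Sult1d1 by 2.33 ± 0.51. Fat markers rose in 1 of 8 (3 adjusted over the list alone), Adrb3 at 1.77 ± 0.47, with a list median of 1.77 (camera adjusted p = 0.0410, and adjusted p = 0.576 with an estimated correlation). The heart-associated myosin gene Myh7 rose by 2.52 ± 0.64, beside cardiac and red blood cell lists that were not called (adjusted p = 0.0586 each). No camera call in this comparison held with an estimated correlation. NK markers were not called (adjusted p = 0.938). Nor were proliferation (adjusted p = 0.305), immunoglobulin constant (0.718), B cell (0.938), T cell (0.0569), mast cell (0.255), eosinophil (0.238), interferon (0.885), lymphoid aggregate (0.805), monocyte (0.0776), dendritic (0.746), endothelial (0.805), fibroblast (0.938), club cell (0.0876) and alveolar macrophage lists (0.173). The B cell and lymphoid aggregate medians (0.15 and 0.09) lay above 0 while their tests pointed down, and the fibroblast median was -0.12 with a mean of 0.07.

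The number of calls with anti-IL-33 depended on the 4 isotype libraries, and also on libraries outside the comparison, which enter the same fit. It was 94 without isotype replicate 1, 935 without replicate 2, 58 without replicate 3 and 683 without replicate 4. Of the 51 named genes called here, 4 stayed called without isotype replicate 3 (Il13ra2, Duoxa1, Ccl11 and Slc26a4) and 18 without replicate 1. Within number range 1 (8 against 3 libraries) 297 genes passed, with Arg1 at -3.47, Ccl11 at -2.78 and Il13 at -4.17. Number range 2 holds 1 isotype library, replicate 4, and there 1 gene passed, with Arg1 at -1.30, Ccl11 at -0.40, Il13 at -0.85 and Il1rl1 at -0.03, while Ccl24 and Retnla turned to 0.79 and 0.31. Against the 2 range 2 libraries without antibody, a comparison added after the result was seen, these genes were at -1.28, -1.47, -1.29, -0.64, -2.43 and -1.20 in the same order, and none passed. Without the 2 libraries that stand apart, both outside these groups, 4639 genes passed, and camera called 11 lists where the main fit called 13. With only these 2 groups in the fit 4153 genes passed.

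Genes changed by 15 weeks of HDM mostly moved the other way with anti-IL-33. Of the 9235 genes called at 15 weeks without antibody, 7976 (86.4%, 95% Clopper-Pearson interval 85.7 to 87.1) had the opposite sign in anti-IL-33 against isotype, a contrast that shares no library with the first. Genes are not independent, so the interval covers counting error only. Of the 4859 genes raised by HDM 4066 were lower with anti-IL-33, and of the 4376 lowered 3910 were higher. In the opposite direction 892 were called and in the same direction 9, where unrelated lists of these sizes would share 309 and 311. Random regroupings of these libraries gave opposite shares from 12.4% to 79.3%. Genes thus move together, and 309 and 311 do not measure chance. The counts of 892 and 9 rested on single libraries. They were 83 opposite and 1 the same without isotype replicate 1, and 819 and 6 without replicate 2. Without replicate 3 they were 46 and 1, and without replicate 4 they were 535 and 19. They were 202 and 2 in number range 1 and 3603 and 78 without the 2 libraries that stand apart, and in range 2, where 1 gene passed in all, none of these genes did. The slope of the anti-IL-33 effect on the HDM effect was -0.28, with -0.28 in number range 1 and -0.21 in range 2, and -0.29 without the 2 libraries that stand apart.

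**Figure D3:**
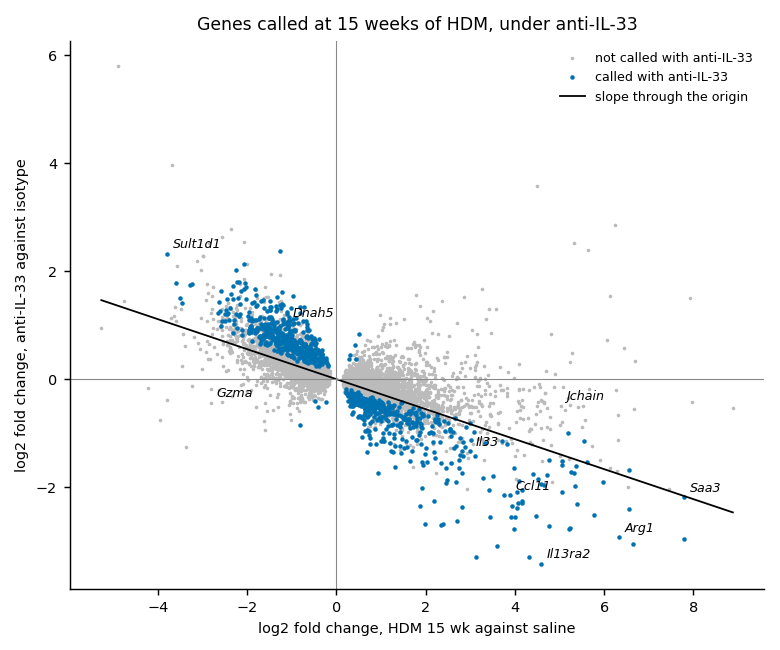
Log2 fold change of anti-IL-33 against isotype (vertical axis) for the 9235 genes called after 15 weeks of HDM, by their log2 fold change against saline (horizontal axis). Points are genes, blue where also called with anti-IL-33, and the line is the slope through the origin, -0.28.

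The isotype control was compared with 15 weeks of HDM without antibody to ask whether the control antibody itself changed the exposed lung. camera called NK and cytotoxic markers higher with the isotype, with a median of 1.05 (adjusted p = 0.00234 with an estimated correlation), though none of the 10 passed over all genes. Gzma averaged 14.6 ± 4.00 CPM (SD, n = 4) with the isotype and 5.08 ± 1.13 CPM (n = 7) without antibody (1.51 ± 0.31, adjusted p = 0.0531), and all 4 isotype libraries were above every library without antibody. Gzmb was at 1.55 ± 0.34 (adjusted p = 0.0962) and Ncr1 at 1.70 ± 0.39 (adjusted p = 0.137). By edgeR no gene passed, with 932 genes at an unadjusted p under 0.05, while DESeq2 called 8 and limma-voom 0.

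Of the 10 NK markers 7 rose adjusted over the list alone. This was the 1 camera call here that held (adjusted p = 2.19e-19, and adjusted p = 0.00234 with an estimated correlation). camera also called interferon response genes up with a median of 0.33 (adjusted p = 4.15e-06, and adjusted p = 0.676 with an estimated correlation). Matrix genes were called down with a median of -0.33 (adjusted p = 0.000428, and adjusted p = 0.999 with an estimated correlation), and immediate early genes down with a median of -0.44 (adjusted p = 3.29e-06, and adjusted p = 0.273 with an estimated correlation). No member of these 3 lists passed over all genes, and adjusted over the list alone 1 immediate early gene fell. Replicate 1 without antibody, which stands apart, differed from the other 6 in the opposite direction to all 3 calls (medians of -1.03, 0.73 and 0.45). As it belongs to the reference group, these deviations move the comparison in the direction of the calls. The matrix list was not called without the 2 libraries that stand apart (adjusted p = 0.0693), while the other 2 lists were. The type 2 (adjusted p = 0.969), alternatively activated macrophage (0.998), alarmin (0.998), goblet (0.393) and neutrophil-attracting lists (0.866) were not called, with Il5 at 0.60 ± 0.56, Il6 at -0.94 ± 0.47 and Pdcd1lg2 at -0.23 ± 0.24. The other 22 lists were not called, and the red blood cell list had a median of 0.18 and a mean of -0.87. Within number range 1 (3 against 5 libraries) 0 genes passed by edgeR and within range 2 (1 against 2) 1 passed, with Gzma at 1.52 and 1.53. Without the 2 libraries that stand apart 1 gene passed.

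The last comparison asked what still differed from saline in lungs that received anti-IL-33 during 15 weeks of HDM. Jchain averaged 3225 ± 1382 CPM (SD, n = 15) against 142 ± 197 CPM (n = 7), a log2 fold change of 4.55 ± 0.54, and Lcn2 1165 ± 813 against 90.8 ± 33.3 CPM (3.73 ± 0.41). Macrophage genes such as Ms4a7 (3.07 ± 0.19) and C1qb (2.07 ± 0.16) stayed above saline in all 15 libraries. The NK cell gene Gzma stayed below it, at -1.75 ± 0.21. edgeR called 3125 genes higher and 2890 lower, with 1289 changed at least 2-fold. After the GC and length correction 3469 were higher and 3644 lower. Of the 6015 genes called in the main fit, 5687 stayed called and all kept their sign. Of the 9235 genes called at 15 weeks without antibody 5262 were called in the same direction here, 3970 were not called and 3 were called the opposite way. Both contrasts use the same 7 saline libraries, so part of this likeness comes from them. What unchanged groups would give was not computed for this pair.

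Plasma cell markers rose in all 10, also adjusted over the list alone (camera adjusted p = 1.30e-11, and adjusted p = 0.0362 with an estimated correlation). Monocyte and interstitial macrophage markers rose in 7 of 13 and fell in 1, the same adjusted over the list alone (adjusted p = 2.50e-09 and, with an estimated correlation, adjusted p = 0.0362). Complement and acute phase genes rose in 10 of 14 (10 rose and 1 fell adjusted over the list alone; adjusted p = 2.95e-08 and, with an estimated correlation, adjusted p = 0.0362). With the immunoglobulin constant list, here Jchain alone (adjusted p = 0.00534 and, with an estimated correlation, 0.0362), these were the 4 calls that held with an estimated correlation. A single gene has no correlation to estimate, so this is no test of the immunoglobulin list, and Jchain is also on the plasma cell list. Proliferation genes rose in 16 of 17 (16 adjusted over the list alone), with Bub1b at 1.79 ± 0.21 (camera adjusted p = 2.89e-09, and adjusted p = 0.120 with an estimated correlation). Neutrophil-attracting mediators rose in 12 of 13 (12 adjusted over the list alone), with Saa3 at 5.77 ± 0.89 and Cxcl1 at 2.53 ± 0.43 (camera adjusted p = 3.07e-06, and adjusted p = 0.208 with an estimated correlation). Alternatively activated macrophage genes rose in 8 of 14 (8 adjusted over the list alone), with Arg1 at 3.87 ± 0.69 (camera adjusted p = 5.23e-05, and adjusted p = 0.120 with an estimated correlation). Type 2 genes rose in 5 of 14 and fell in 1, the same adjusted over the list alone, with Ccl8 at 4.21 ± 0.39 and Ccl11 at 1.96 ± 0.39 (camera adjusted p = 0.0294, and adjusted p = 0.351 with an estimated correlation). Goblet genes rose in 9 of 15 (9 adjusted over the list alone), with Itln1, an intelectin, at 5.47 ± 0.73 (camera adjusted p = 0.000327, and adjusted p = 0.269 with an estimated correlation). T cell markers rose in 7 of 14 and fell in 1, the same adjusted over the list alone, with Foxp3 at 1.47 ± 0.20 (camera adjusted p = 0.00248, and adjusted p = 0.351 with an estimated correlation). Eosinophil markers rose in 4 of 9 and fell in 1, the same adjusted over the list alone, with Prg2 at 3.89 ± 0.34 (camera adjusted p = 0.0373, and adjusted p = 0.215 with an estimated correlation).

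NK markers fell in 9 of 10 (9 adjusted over the list alone; camera adjusted p = 3.64e-07, and adjusted p = 0.0669 with an estimated correlation). Type I alveolar markers fell in 10 of 11 (10 adjusted over the list alone), with Hopx at -1.18 ± 0.17 (camera adjusted p = 3.64e-07, and adjusted p = 0.0669 with an estimated correlation), and endothelial markers in 11 of 13 (11 adjusted over the list alone), with Tek at -1.32 ± 0.21 (camera adjusted p = 3.64e-07, and adjusted p = 0.0789 with an estimated correlation). Cardiac muscle genes fell beside them in 5 of 10 (7 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0446, and adjusted p = 0.479 with an estimated correlation), while red blood cell (adjusted p = 0.233) and fat markers (adjusted p = 0.754) were not called. Matrix genes were not called as a list (adjusted p = 0.208), with Tnc at 1.02 ± 0.23. Neutrophil markers (0.902), the alarmin list (0.495), interferon (0.754), mast cell (0.331), B cell (0.0921), club cell (0.0649) and immediate early genes (0.158) were not called. The interferon and neutrophil medians (-0.20 and -0.18) and means (0.23 and 0.24) differed in sign. Lymphoid aggregate, alveolar macrophage, dendritic and type II alveolar lists were called up (adjusted p = 0.0120, 0.0229, 0.00160 and 0.00257), with estimated-correlation adjusted p = 0.286, 0.351, 0.120 and 0.215. Ciliated and fibroblast lists were called down (adjusted p = 0.0461 and 0.0120), with estimated-correlation adjusted p = 0.569 and 0.297. Within number range 1 (8 against 2 libraries) 578 genes passed and within range 2 (7 against 5) 7178, with Jchain at 6.85 and 3.87 and Gzma at -1.38 and -1.89. Without the 2 libraries that stand apart 7902 genes passed, and camera called 17 lists where the main fit called 21.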

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

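The tests of the share of 1 ID, of tissue pieces, of GC content and gene length, of carried-over RNA, of airway tissue and of a mislabelled sample were chosen or amended only after the result was seen.

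Of 104 sets of values tested for a library far from the others of its group, 22 had one. Chance gives about 1 in 20 for independent normal values, which CPM of related genes are not. The 15 anti-IL-33 libraries were not tested, as the test covered the smaller groups only. In 4-week HDM replicate 3 Ccl11 (164 CPM), Retnla (15367 CPM), Saa3 (171 CPM), S100a8 (79.2 CPM), Gzma (49.2 CPM) and Scgb1a1 (15952 CPM) were each above the other 9 libraries. In 4-week HDM replicate 5 Cxcl2 was high (6.64 CPM). In 15-week HDM replicate 4 Il1rl1 (62.2 CPM), Ccl24 (22.3 CPM), Ccl8 (100.1 CPM), Arg1 (527 CPM) and Timp1 (240 CPM) were above the other 6. In isotype replicate 4 Ccl8 was low at 39.2 CPM and the total count high at 10.2 M. Saline replicate 5 was high for Il33 (133 CPM) and Jchain (563 CPM), and saline replicate 3 for Scgb1a1 (24026 CPM) and Foxj1 (160 CPM). Total counts were low in 15-week HDM replicate 2, at 4.91 M. In 15-week HDM replicate 1 Il33 was low (117 CPM), Foxj1 high (143 CPM) and ID 100861531 held 13.3% of counts.

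The HDM effects at 15 and 4 weeks, both against the same saline libraries without a time label, differed in 3334 genes by a direct test of the difference. In 24 of these the effects were called in opposite directions. Among these 24, Csf3r, Nlrp3, Trem1 and P2ry13, genes of neutrophils and other myeloid cells, were below saline at 4 weeks (-0.58, -0.71, -0.69 and -0.64) and above it at 15 weeks (0.61, 0.69, 1.07 and 1.06). They were picked after their values were seen. Kcnn3 (-1.02, then 1.06) and Ptprf (-0.35, then 0.84) turned the same way, and no common theme of the 24 was tested. Cd40 went from 0.62 to -0.42.

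HDM15wk replicate 1, the first of the 15-week libraries without antibody, lay apart from the other 6, with a median absolute deviation of 0.669 (log2) where the highest of the others was 0.236. Leaving out the ID that takes 13.3% of its counts, the test first written, left the deviation at 0.668, or 2.84 times the highest other, which says nothing, since removing 1 ID hardly moves a median over all genes. A large share lowers all other genes by 1 common factor, which cannot change their spread about the library's own median. That spread was 2.60 times the highest other without the ID (0.668 against 0.257), which argues against the share as the whole cause. Its correlation with the isotype mean was 0.860, above the 0.851 with its own group, which meets what was first written for a mislabelled sample. The condition against it was amended after this was seen: each of its correlations with the 5 group means was below the 0.959 to 0.987 that the other 6 libraries have with their own group, which argues against a wrong label alone. GC bias may be the source, since its deviation correlated with transcript GC content at 0.813 (others -0.400 to 0.540) and fell to 0.308 after GC content and length were taken out. No biological explanation was tested.

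Between the number ranges 688 genes were called, 81 of them at least 2-fold, and 73 of the 81 were lower in range 2. Different counting of overlapping genes may be the source, since 72.4% of the 76 annotated genes overlap exons of another gene against 35.8% of the other genes (odds ratio 4.69, 95% interval 2.79 to 8.17). For overlap on the opposite strand the odds ratio was 6.12 and for the same strand 1.24 (0.515 to 2.60). A difference in tissue pieces stays open as well, since the largest median difference of a cell type or tissue list was 0.712 in size, in fat markers, though only 1 of the 81 genes is on such a list. Every group has libraries in both ranges, and the fit has a term for them.

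Goblet cell genes varied widely between saline libraries, with Clca1 at 332, 0.674, 754, 3.24, 425, 24.1 and 1.08 CPM in replicates 1 to 7. Other genes, picked after their values were seen, were also highest in replicates 1, 3 and 5. Ccl11 was at 4.53, 7.67 and 6.82 CPM there (others at most 2.16) and Ccl8 at 2.67, 3.18 and 4.802 CPM (at most 1.22). Retnla was at 775, 1634 and 692 CPM (at most 138), and Il13, near the floor, had counts only there. Arg1 did not follow, with its lowest value, 2.11 CPM, in replicate 5. The saline baseline was thus uneven for such genes in each contrast with saline. RNA carried over from 4-week libraries is argued against as the whole cause, since the median rise of 4 HDM genes reached at most 0.169 of what it would give in replicates 1, 3 and 5. Of these genes Retnla came nearer, with 1634 CPM in replicate 3 where carry-over would give 3115, while Arg1 was at 3.18 CPM where it would give 129. More airway tissue is argued against as the whole cause, since club and ciliated markers had a median log2 range of 0.984, or 0.101 of that of Clca1. Scgb3a1 had the highest, 3.18, and replicate 3, with the most Clca1, was also high for Scgb1a1 and Foxj1, so a part stays open. A biological difference between saline mice stays open and may be the source, but no design variable tests it.

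The same libraries were regrouped at random within number ranges, in 22 splits with the real one. For 5 comparisons only the real split reached the real gene count. A share of 1 in 22 is the smallest these splits can give, and there was no adjustment for the number of patterns tested. They make chance unlikely for these counts and do not exclude it. The real and highest other counts were 8866 and 3697 at 4 weeks, 9235 and 5935 at 15 weeks, 3334 and 268 for 15 against 4 weeks, 1046 and 28 for anti-IL-33 against isotype, and 6015 and 47 for anti-IL-33 against saline. Each was reached by 1 of the splits, the real one. Isotype against no antibody had 0 genes by edgeR (932 at an unadjusted p under 0.05, 8 by DESeq2 and 0 by limma-voom). Every split reaches a count of 0, so the 22 splits say nothing about chance there. The highest of the others called 1650, which points to a structure of the samples that no test here identified. The share moved back (86.4% against 79.3%) and its slope (-0.28 against -0.13) were also reached by the real split alone. For the overlap of 4 and 15 weeks (6867 against 0) the splits mixed the saline, 4-week and 15-week libraries, which takes both HDM effects away. A shared count near 0 was thus fixed in advance, and it says nothing about how far the real effects overlap. Among the counts of lists, only the real count for 15 against 4 weeks was reached by the real split alone (21 against 17). Other splits reached it too at 4 weeks, at 15 weeks and for anti-IL-33 against saline (21 against 21 in each, 2 of 22 splits). So they did for anti-IL-33 against isotype (13 against 16, 7 splits) and isotype against no antibody (4 against 16, 11 splits). The median of the other splits was 13 lists at 4 weeks, 10 at 15 weeks and 5 for 15 against 4 weeks. It was 11 for anti-IL-33 against isotype, 3 for isotype against no antibody and 14 for anti-IL-33 against saline. At the preset correlation camera thus calls many lists in regrouped libraries, so its p-values alone are weak evidence. The regrouped libraries still hold the real differences between the mixed groups, so these list counts are not those of unchanged groups. A second set of 21 splits was drawn after the first was seen and is not used here. In it the real split also stood alone for the list counts at 15 weeks and for anti-IL-33 against saline, so these outcomes depend on the draw.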

How the results depend on the processing

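The settings without the 2 libraries that stand apart, and with counts corrected for GC content and gene length, were chosen only after the result was seen.

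Of 5179 values of single named genes under alternatives, 4664 kept the side of the threshold (18 of them changed sign, uncalled in both fits), 445 kept the direction and lost the call, 65 gained it and 5, called in at least 1 fit, reversed. The reversed values were Myh1 at 4 weeks (-1.56 in number range 1, -0.95 with a surrogate variable), Creb3l1 for 15 against 4 weeks (-0.016 in range 2), and Ccl24 (0.79) and Retnla (0.31) for anti-IL-33 against isotype in range 2, which holds 1 isotype library. Lists reversed in range 2 were matrix (-0.22) and immediate early genes (-0.23) for 15 against 4 weeks, interferon (-0.37), T cell (-0.27) and fibroblast (0.50) for anti-IL-33 against isotype, and complement (0.18) for isotype against no antibody. In range 1 the interferon list reversed for anti-IL-33 against saline (0.20). Where no other reason is given, the cause was not tested.

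Counts of changed genes fell in number range 1 to 2309 at 4 weeks, 4194 at 15 weeks, 1409 for 15 against 4 weeks, 297 for anti-IL-33 against isotype and 578 for anti-IL-33 against saline. In range 2 they were 149 for 15 against 4 weeks and 1 for anti-IL-33 against isotype. At a change of at least 2-fold they were 2027, 2991, 507, 277 and 1289, in the order of range 1, and the overlap of 4 and 15 weeks was 1637. With only the 2 groups in the fit, 1206 genes passed for 15 against 4 weeks and 4153 for anti-IL-33 against isotype. The latter count was 687 with no filter, 4639 without the 2 libraries that stand apart, 1704 with DESeq2, 5588 against libraries without antibody, 6280 against these and isotype together, and 58 to 935 with an isotype library left out (replicates 3 and 2). For isotype against no antibody it was 7 with no filter, 6 at a mean of at least 1 CPM, 4 without the range term, 1 in range 2, 1 without the libraries that stand apart, 8 with a surrogate variable, 8 with DESeq2 and 0 to 11 with an isotype library left out (replicates 2 and 1), against 0 by edgeR (932 unadjusted, 0 with limma-voom).

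Calls of lists changed most with an estimated correlation, to 3 at 4 weeks, 0 at 15 weeks, 0 for 15 against 4 weeks, 0 for anti-IL-33 against isotype, 1 for isotype against no antibody and 4 for anti-IL-33 against saline, 8 in all against 101. For isotype against no antibody fry called 1 and range 2 gave 8. The share of 15-week genes moved back was 89.1% in range 1, 84.6% in range 2, 85.1% without the libraries that stand apart, 85.0% with GC content and length corrected, 88.6% for genes chosen at 4 weeks, 89.3% for genes of at least 2-fold, and 83.7% to 87.2% with an isotype library left out. With GC content and gene length corrected, 799 of the 1046 genes called for anti-IL-33 against isotype stayed called, and 1044 kept their sign. No list was tested under that correction. Total counts of 4.80 to 12.6 M limit what can be said of genes near 0, such as Epx with 44 counts in all.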

Other observations

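The comparison of anti-IL-33 with libraries without antibody within each number range, and the genes named in this part, were chosen only after the result was seen. The test of the Ifi202b region was set down before its result.

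Awat1, an acyltransferase gene of lipid synthesis, averaged 0.189 ± 0.403 CPM (SD, n = 7) in saline, 16.7 ± 9.34 (n = 10) after 4 weeks of HDM and 54.4 ± 18.6 (n = 7) after 15 weeks. It averaged 57.7 ± 17.4 (n = 4) with the isotype and 43.1 ± 34.97 (n = 15) with anti-IL-33. Fga averaged 0.663 ± 0.927 CPM in saline, 0.822 ± 0.860 at 4 weeks, 18.4 ± 6.45 at 15 weeks, 16.96 ± 1.88 with the isotype and 6.78 ± 5.78 with anti-IL-33.

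Anti-IL-33 against the 15-week libraries without antibody gave 3561 changed genes in number range 1 (8 against 5 libraries) and 4 in range 2 (7 against 2). Arg1, Ccl11, Il13 and Ccl24 were at -2.99, -2.34, -3.91 and -3.80 in range 1, where all 4 passed, and at -1.28, -1.47, -1.29 and -2.43 in range 2, where none did. Il33 in single anti-IL-33 libraries ran from 21.5 CPM in replicate 8 to 511 CPM in replicate 1.

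Ifi202b, an interferon-inducible gene, was above 5 CPM in 3 of the 4-week libraries, all of number range 1. A candidate explanation is a stretch of chromosome 1 from the mixed strain background. Of 173 genes within 10 Mb, 2 differed between these libraries and the rest at an unadjusted p under 0.001, Ccdc190 (2.80, adjusted p = 0.00061) and Dusp23 (-1.15, adjusted p = 0.835), against 0.0650% of other genes (odds ratio 17.96, 95% interval 1.90 to 85.3). This rests on 2 genes, and only Ccdc190 passes the adjusted test, so it stays a weak hypothesis.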
